A study of Mus musculus with 18 samples.

How the data were processed

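RNA was measured on 18 2-colour Agilent arrays, 3 for each of 6 groups: the murine triple-negative breast cancer lines E-Wnt, M-Wnt and metM-Wnt, each grown for 72 h in control medium (2.2 µM folic acid) or in folic acid-free medium (0 µM). Per the labels, total RNA of the cells was made into Cy5-labelled cRNA (red) and hybridised with Cy3-labelled cRNA of NIH3T3 mouse fibroblasts (green), which served as the common reference on every array. The dyes were not swapped, so every ratio is red over green, sample over reference, and a dye effect common to all arrays cancels in each comparison. The labels give regular serum for control medium and dialyzed serum for folic acid-free medium, so the serum changed together with the folic acid in every withdrawal comparison. The series' design text calls the 3 arrays of a group biological replicates. Its design text gives the folic acid concentration in another unit (mM) than the labels (µM), and the labels' unit is used here.

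The deposited scanner files hold spot and background intensity on a linear scale for both channels, quantified with Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes. They also hold processed intensity values, background-subtracted and dye-normalised by Feature Extraction per the file headers. The deposited series table holds log10 ratios: each of its columns equalled the Feature Extraction log10 ratio of its own array within 0.005, with 5 columns rounded and a median of 0 in every column. Its scale and direction are therefore known from the scanner files. The array design's genome build plays no part here, and no coordinates are given.

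Each array held 165888 spots, of which 4848 were control spots, and 80520 probes with 2 spots each. From the scanner intensities, the background was corrected with normexp (offset 50), log2 ratios were normalised within each array by loess with weight 0 for control spots and spots with an outlier mark, and the spots of a probe were averaged, all in limma 3.58.1 under R 4.3.3 with the data.table package at version 1.17.8. Figures were drawn with matplotlib 3.10.9. A probe was kept when both of its spots were well above background in the red channel on all 3 arrays of at least 1 group, which left 41089 probes; 20 probes without a usable spot on some array were left out. Signal over background sets what can be measured: between 40.9% and 53.7% of probes per array were well above background in red, and no spot was saturated (0 on every array). The number of arrays limits the precision.

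The files do not pair probes with gene names. Names were taken only where a probe's ID contains a mouse sequence accession that the RefSeq gene table used here (assembly GRCm38.p6) lists: 19687 probes carry such an accession, 220 of them matched 157 gene symbols (182 through a transcript accession and 38 through a synonym), and 0 matched several genes. All 220 have IDs that start with Mm_ncRNA, so a named value is that of a probe whose ID carries an accession of the gene. Whether it reads the messenger RNA, a non-coding transcript or the opposite strand was not checked, and what is said of a gene's protein describes the gene, not the probe. Probes of a named gene were averaged, which gave 41079 features: 74 named genes and otherwise single probes. A feature below is therefore a probe unless a gene is named, and "genes" in the planned design are features here. A probe ID whose text contains an accession is not printed, which leaves out the probe that ranked second among those higher in metM-Wnt.

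The 41079 features were fitted with limma (lmFit and eBayes, no trend, not robust) in a single model of 6 group means over the 18 arrays, which share an estimate of the spread with 12 residual and 3.97 prior degrees of freedom. Tests were 2-sided, and a feature is called at a Benjamini-Hochberg adjusted p under 0.05 over all features. The 9 comparisons were withdrawal against control in each line and averaged over the lines, M-Wnt against E-Wnt and metM-Wnt against M-Wnt in control medium, and the 3 differences in withdrawal response between lines (interaction contrasts). Changes are log2 differences ± the model's SE with n = 3 arrays per group. Every adjusted p in the text is from this limma model unless a set test is named.

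The rule for named genes, fixed before the data were examined together with the comparisons, alternatives and gene lists, took up to 6 called genes higher and 6 lower per withdrawal or line comparison (3 each way for differences in response), by size of change, whose 3 arrays of a group all lay beyond the 3 of the other and whose probes had a single sign. For the average over the lines and for differences in response only the sign criterion was applied. Since few features have names, at most 2 probe IDs each way were added per comparison by the same ranking, a choice made after the files were seen. Of 31 fixed gene lists, 5 had a tested member: folate transport and one-carbon enzymes (Gcsh), heat shock (Hspb1 and Hspd1), endoplasmic reticulum chaperones (Dnajb9), fatty acid synthesis (Acaca), and G2/M and mitosis (Prc1). The heat shock list was labelled cytosolic when it was fixed, and that label is not used for its members here. All lists had been fixed by name in advance. The 5 lists were tested with camera (preset correlation 0.01, and estimated) and fry, and with cameraPR under the alternatives. With at most 2 tested members such a test says little about a list. Cdh1, Epcam, Vim, Zeb1 and Wnt1, planned as identity markers of the lines, were not named on any probe and are not analysed here.

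The pipeline was tested on simulated arrays with 200 changed features. With each feature's own SD in each line, 89.6% of simulated 2-fold changes were recovered in E-Wnt, 71.6% in M-Wnt and 76.1% in metM-Wnt, and 326, 4 and 49 unchanged features were called. A second simulation, added after the first was seen, used moderated SDs scaled to each line: recovery was 80.6%, 89.6% and 76.1%, and 123, 1 and 1 unchanged features were called. The shared estimate of the spread thus calls too many features in E-Wnt, whose arrays varied most, as is stated beside that comparison.

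The alternatives tried were: no background subtraction; Agilent processed signals; the series table; loess followed by Aquantile; median centring without loess; the red channel alone with quantile normalisation; no filter, or a filter for all 18 arrays; the brightest probe or the median of a gene's probes; slide as a fixed block, as a random block, or only arrays of the slide that holds both media; the replicate number as a block; array weights; a minimum 2-fold change; robust eBayes with trend; only the groups compared; and each array left out in turn. Slides, from the file headers, held 4 arrays each except slide 5, which held 2: slide 1 the E-Wnt controls and E-Wnt withdrawal 1, slide 2 E-Wnt withdrawal 2 and 3 and M-Wnt control 1 and 2, slide 3 M-Wnt control 3 and the M-Wnt withdrawal arrays, slide 4 the metM-Wnt controls and metM-Wnt withdrawal 1, and slide 5 metM-Wnt withdrawal 2 and 3. Each slide was scanned in a single session, so slide and scan cannot be separated.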

Results

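The data are log2 ratios of RNA in cultured mouse mammary tumour cells to a common NIH3T3 fibroblast reference, on 18 arrays in 6 groups of 3: the lines M-Wnt, metM-Wnt and E-Wnt after 72 h in control medium with 2.2 µM folic acid or in medium without it. The series set out to find how folic acid withdrawal changes expression in 3 triple-negative breast cancer lines. Of 80520 probes per array, 41089 were bright enough to test, as 41079 features, of which 74 are genes that could be named and the others single probes known by their IDs. Mean red signal per array ranged from 1964 to 6649 and mean green signal from 3371 to 4618. Red signal was lower on the M-Wnt withdrawal arrays (3722, 3418 and 1964) than on the M-Wnt control arrays (5134, 5170 and 4213). It was lower too on the metM-Wnt control arrays (3502, 3393 and 3268), and lower still on the metM-Wnt withdrawal arrays (2260, 2784 and 2837). Whether this signal difference bears on comparisons of these groups was not tested. Green-channel signals of the common reference correlated at 0.989 to 0.998 between arrays, across features. Replicate arrays varied most in E-Wnt, with a median SD of 0.222 log2 units per feature against 0.133 in M-Wnt and 0.166 in metM-Wnt. The medium without folic acid also contained dialyzed serum in place of regular serum, so each withdrawal comparison covers both changes. The named genes are read by probes whose IDs start with Mm_ncRNA and carry an accession of the gene, and which strand or transcript they detect was not checked. Each named gene called within a line or between lines in control medium had all 3 arrays of a group beyond the 3 of the other, which chance gives for 10% of features; this was not required for the average or the differences in response.

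Withdrawal against control in M-Wnt asks how these cells respond to losing folic acid. Hspb1, a small heat shock protein that keeps unfolded proteins from aggregating, rose 2.44-fold (log2 change 1.29 ± 0.18 SE, n = 3 per group, adjusted p = 0.00016). Gcsh, the H protein of the mitochondrial glycine cleavage system that passes one-carbon units to folate, fell by 0.82 on the log2 scale (SE 0.23, adjusted p = 0.023). Tmem41b, an endoplasmic reticulum membrane protein needed for autophagosome formation, fell by 0.94 (SE 0.17, adjusted p = 0.0011). Pdcd10 fell by 0.62, the ADP-ribose hydrolase Macrod2 by 0.56, the RNA polymerase I subunit Twistnb by 0.53 and the splicing factor Srsf10 by 0.48, with adjusted p from 0.0094 to 0.014. The Rab GTPase-activating protein Tbc1d16 rose by 0.54 (adjusted p = 0.029) and the secreted protein Wfdc18 by 0.52 (adjusted p = 0.037). These rises depended on the scaling. Median centring in place of loess gave 0.07 for Tbc1d16 and -0.10 for Wfdc18, the red channel alone 0.10 and 0.04, and processed signals 0.45 and 0.32, none of them called. Tbc1d16 was also not called with the filter for all 18 arrays (0.31). Of the list of heat shock genes, Hspb1 rose and Hspd1 did not pass (-0.03, adjusted p = 0.92). The single tested folate gene, Gcsh, fell, while the chaperone Dnajb9 (0.13, adjusted p = 0.51), the fatty acid synthesis gene Acaca (-0.44, adjusted p = 0.20) and the mitosis gene Prc1 (-0.36, adjusted p = 0.68) did not pass. Neither the heat shock nor the folate list passed camera (adjusted p = 0.34 for each, and 0.45 with an estimated correlation). Adjusted over the list alone, 1 heat shock member and the 1 folate member were under 0.05 (limma). For a list of 1 tested member this is the unadjusted p. Across all features 7563 were called, 18.4% of those tested: 4114 higher and 3449 lower, and 1011 by at least 2-fold, of which 732 were higher. Probes A_51_P387123 and A_52_P653054 rose most, by 4.91 ± 0.53 and 4.82 ± 0.57, and A_51_P184680 and A_52_P348287 fell most, by -2.91 ± 0.11 and -2.69 ± 0.15. Of 1602 transcripts read by at least 2 probes, 434 had a called probe, 231 had all probes called with a single sign, and 0 had probes called in opposite directions.

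The direction of the M-Wnt calls depended on the scaling: 54.4% were higher after loess, 37.6% of 6211 with Agilent processed signals, 38.7% of 6635 with the red channel alone, and 7.91% of 6223 with median centring, where Hspb1 also lost its call (0.54, adjusted p = 0.29). The M-Wnt count was 2230 within the slide that holds both media (a single control array there), 2023 with slide as a fixed block, 4771 with a replicate block, 25558 with array weights, 14984 in a fit of the M-Wnt arrays alone, 4192 and 3994 without M-Wnt control replicate 2 or 3, and 4504 and 4551 without M-Wnt withdrawal replicate 2 or 3. Leaving out M-Wnt control replicate 3 ended the calls of Gcsh (-0.68), Pdcd10 (-0.57), Macrod2 (-0.49), Twistnb (-0.49), Srsf10 (-0.40), Tbc1d16 (0.47) and Wfdc18 (0.49), but not those of Hspb1 or Tmem41b. Slide as a fixed block ended the calls of the same genes (Gcsh -1.12, Pdcd10 -0.73, Macrod2 -0.68, Twistnb -0.62, Srsf10 -0.64, Tbc1d16 0.68, Wfdc18 0.60), again not those of Hspb1 or Tmem41b.

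**Figure D1:**
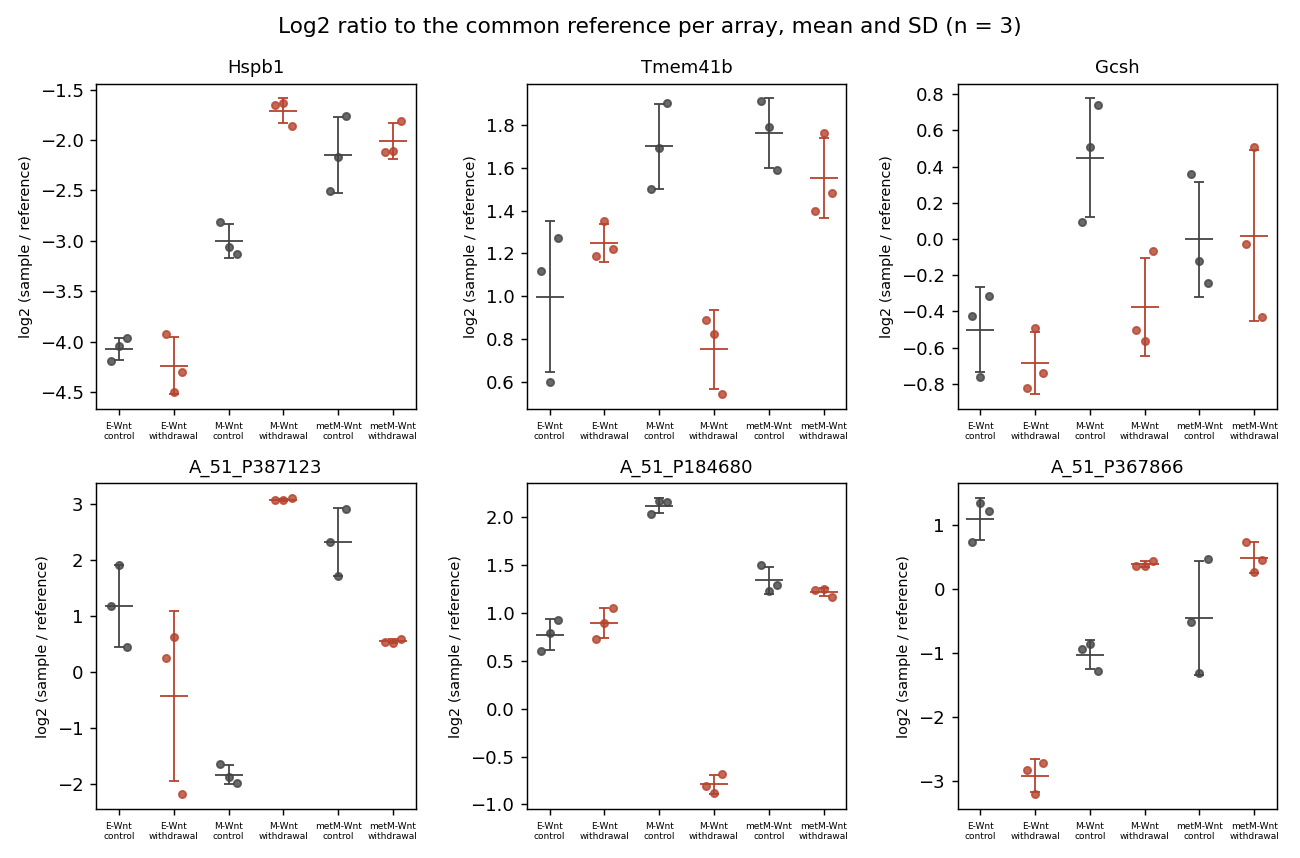
Log2 ratio to the common reference (y axis) on each array (points) for 3 named genes and 3 probes in the 6 groups, with mean and SD (bars, n = 3). Hspb1 lay at -3.00 in M-Wnt control and -1.71 in M-Wnt withdrawal arrays, while its E-Wnt and metM-Wnt groups overlapped between media.

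Withdrawal against control in metM-Wnt asks the same of the metM-Wnt line. None of the 74 named genes was called by limma: Hspb1 changed by 0.13 (adjusted p = 0.82) and Gcsh by 0.02 (adjusted p = 0.99). None of the 5 tested lists passed camera. Dnajb9, the only tested member of the list of endoplasmic reticulum chaperones, had an unadjusted p under 0.05 (limma) but was not called over all features. Across all features 166 were called (5433 at an unadjusted p under 0.05), 67 higher and 99 lower, 42 of them by at least 2-fold. Probe A_51_P264769 rose by 1.83 ± 0.29 (adjusted p = 0.018), and A_51_P164219 and A_51_P494403 fell, by -2.19 ± 0.33 (adjusted p = 0.016) and -2.03 ± 0.36 (adjusted p = 0.029). The call of A_51_P264769 was lost without metM-Wnt control replicate 1 (1.73) or withdrawal replicate 2 (1.96) or 3 (1.66). That of A_51_P164219 was lost without the same arrays (-2.05, -2.18 and -2.13), and that of A_51_P494403 without these (-2.07, -2.06 and -1.96) or control replicate 3 (-1.82). Probes called higher in both M-Wnt and metM-Wnt numbered 39, against 6.7 expected of independent lists, and probes called lower in both 25, against 8.3. Another 38 probes, A_51_P164219 and A_51_P494403 among them, were called higher in M-Wnt and lower in metM-Wnt (9.9 expected), and 3 lower in M-Wnt and higher in metM-Wnt (5.6 expected). No call was left (0 of 3276 and 3672 at an unadjusted p under 0.05) with slide as a fixed block or within the slide that holds both media, nor in a fit of the 6 metM-Wnt arrays alone (5510), and 31 were left with a replicate block. The count was 20, 81 and 75 without metM-Wnt control replicate 1, 2 or 3 and 17 and 44 without metM-Wnt withdrawal replicate 2 or 3; 40.4% of calls were higher after loess, 20.0% of 285 with processed signals, 19.9% of 292 in the series table and 5.56% of 18 with median centring.

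Withdrawal against control in E-Wnt asks the same of the E-Wnt line. None of the 74 named genes was called by limma: Hspb1 changed by -0.18 (adjusted p = 0.87), Gcsh by -0.19 (adjusted p = 0.91), and no list passed camera. Probe A_51_P367866 fell by -4.02 ± 0.31 (adjusted p = 2.7e-05), and in M-Wnt the same probe rose by 1.41 ± 0.31. Probe A_52_P262219 fell by -3.23 ± 0.27 (adjusted p = 3.7e-05), while A_51_P468249 and A_52_P290732 rose by 1.21 ± 0.19 and 1.01 ± 0.16 (adjusted p = 0.036 for each). The calls of these rises were lost in 9 of 24 and 13 of 23 settings. A_51_P468249 ranged from 0.81 to 1.43 and lost its call without E-Wnt control replicate 1 (1.14) or 2 (1.13). A_52_P290732 ranged from 0.70 to 1.87 and lost it without E-Wnt control replicate 1 (1.06), 2 (1.01) or 3 (0.96) or withdrawal replicate 1 (0.89). Within slides the falls of A_51_P367866 (-3.93, adjusted p = 0.063) and A_52_P262219 (-3.25, adjusted p = 0.059) lost their calls. That of A_52_P262219 was also lost in a fit of the E-Wnt arrays alone. Across all features 16 were called (3292 at an unadjusted p under 0.05), 2 higher and 14 lower; 7 lower and 0 higher with median centring. Simulated E-Wnt arrays gave 123 or 326 false calls, more than were observed, and only 1 call was left in a fit of the E-Wnt arrays alone and 1 within the slide that holds both media (6 with slide as a fixed block, 9 with a replicate block). The count rose to 159 without E-Wnt withdrawal replicate 3, the array farthest from its group (SD of its deviations 0.379), and to 67 without E-Wnt withdrawal replicate 2, and it was 9 and 6 without E-Wnt control replicate 1 or 2.

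The change after withdrawal averaged over the 3 lines was 0.40 ± 0.085 for Rps23rg1 (adjusted p = 0.012) and 0.41 ± 0.10 for Hspb1 (adjusted p = 0.024). It was 0.33 ± 0.092 for Tbc1d16 (adjusted p = 0.045) and -0.20 ± 0.058 for Txndc9, a thioredoxin-domain protein (adjusted p = 0.050). The means of Rps23rg1 and Tbc1d16 were higher after withdrawal in each line. Neither gene was called in E-Wnt or metM-Wnt, and Rps23rg1 was not called in M-Wnt either. The mean of Hspb1 went from -3 to -1.71 in M-Wnt, but from -4.07 to -4.24 in E-Wnt and from -2.15 to -2.01 in metM-Wnt. Txndc9 hardly changed in metM-Wnt (0.25 to 0.257). The rise of Rps23rg1 was kept with each of the 18 arrays left out in turn; Hspb1 lost its call without M-Wnt control replicate 2 or 3 or M-Wnt withdrawal replicate 2, Tbc1d16 without any of 14 arrays, and Txndc9 without any of 15. Median centring ended the calls of Rps23rg1 (0.25, adjusted p = 0.28), Hspb1 (0.09, adjusted p = 0.82), Tbc1d16 (0.11) and Txndc9 (-0.52). Slide as a fixed block ended those of Rps23rg1 (0.49, adjusted p = 0.061), Hspb1 (0.53, adjusted p = 0.098), Tbc1d16 (0.30) and Txndc9 (-0.23), as did within-slide values. The red channel alone ended those of Rps23rg1 (0.16, adjusted p = 0.38), Tbc1d16 (0.02) and Txndc9 (-0.19). A replicate block ended those of Rps23rg1 (adjusted p = 0.057), Tbc1d16 and Txndc9, and processed signals those of Tbc1d16 (0.14) and Txndc9 (-0.21). Gcsh changed by -0.33 (adjusted p = 0.15) and Prc1 by -0.35 (adjusted p = 0.55). The lists did not pass camera. Adjusted over the list alone, Hspb1 was under 0.05 (limma). Dnajb9 and Gcsh were each the only tested member of their list, and their unadjusted p was under 0.05. Neither was called over all features. Probes A_51_P377045 and A_52_P416123 rose by 1.25 ± 0.26 and 1.23 ± 0.23 but lost their calls with slide as a fixed block (1.38, adjusted p = 0.10, and 1.34, adjusted p = 0.090) or within slides. The averages of A_51_P184680 and A_52_P348287, -0.97 ± 0.066 and -0.95 ± 0.087, were carried by M-Wnt. The mean of A_51_P184680 went from 2.12 to -0.791 in M-Wnt, from 0.773 to 0.893 in E-Wnt and from 1.34 to 1.22 in metM-Wnt. In total 2841 features were called, 1365 higher and 1476 lower, 12 of them by at least 2-fold. Of the 2841 features, 2416 were also called in M-Wnt, and 64.8% had a single sign in all 3 lines, against 26.7% of all features. The 2841 were chosen by their mean change over the same arrays, which by itself favours a single sign. The 26.7% is therefore not the share to be had without a shared response, and no shared response is read from the difference. Calls higher made up 48.0% after loess, 31.9% of 2320 with processed signals, 31.8% of 2322 in the series table and 7.30% of 507 with median centring. The count was 225 with slide as a fixed block, 201 within slides, 1038 with a replicate block, 1717 and 1719 without M-Wnt control replicate 2 or 3, 1841 and 1838 without M-Wnt withdrawal replicate 2 or 3, and 1739 without metM-Wnt withdrawal replicate 1.

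**Figure D2:**
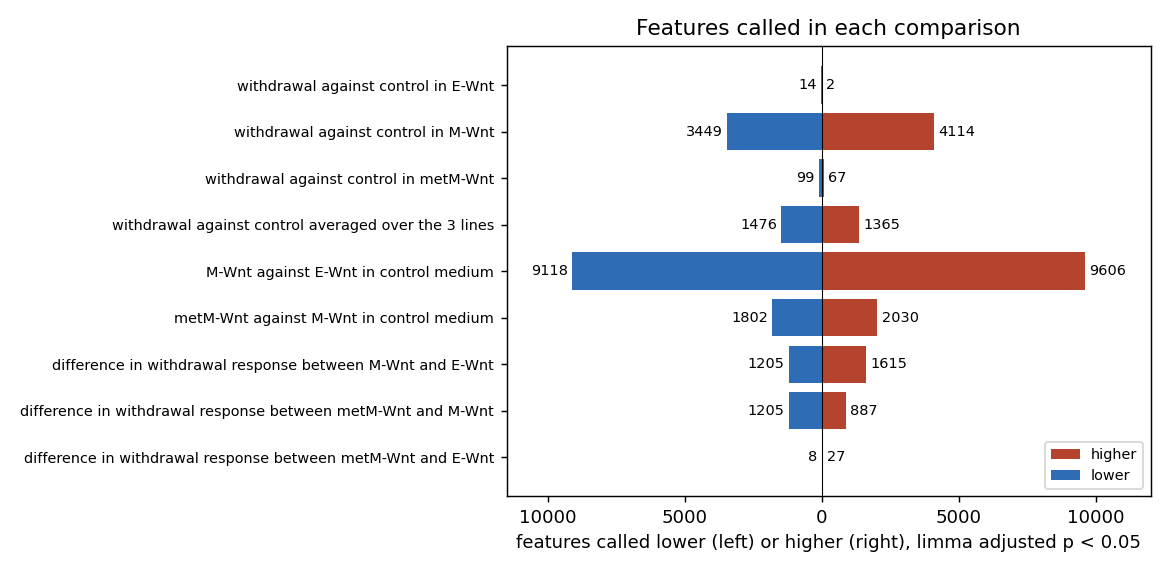
Number of features called higher (right) or lower (left) in each of the 9 comparisons (x axis, limma). M-Wnt had 7563 calls after withdrawal against 16 in E-Wnt and 166 in metM-Wnt.

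M-Wnt against E-Wnt in control medium asks how the lines differ before withdrawal. Tbc1d16 was 7.55-fold lower in M-Wnt (-2.92 ± 0.16, adjusted p = 1.6e-10), and ezrin (Ezr), which links actin to the plasma membrane, was 2.90-fold lower (-1.53 ± 0.28, adjusted p = 0.00022). Pate14 (-0.94), the ATP synthase component Atp5md (-0.75), the aldo-keto reductase Akr1b10 (-0.73) and the peptidyl-prolyl isomerase Ppid (-0.60) were lower too, with adjusted p from 0.00012 to 0.010. The selenoprotein Selenoh was 3.21-fold higher in M-Wnt (1.68 ± 0.31, adjusted p = 0.00024), Ssbp2, a single-stranded DNA binding protein, 2.60-fold (1.38 ± 0.11), Slfn3 2.28-fold (1.19 ± 0.20), Hspb1 2.10-fold (1.07 ± 0.18) and Srsf10 2.08-fold (1.06 ± 0.12). The ubiquitin ligase Rnf125 was not well above background in any E-Wnt control array and was called higher in M-Wnt (adjusted p = 0.0012), with no size given because the E-Wnt values lie at background. Gcsh was higher in M-Wnt by 0.95 ± 0.23 (adjusted p = 0.0030), and Prc1 did not pass (0.86, adjusted p = 0.25). Of the 74 named genes 33 were called, 19 higher and 14 lower. Probes A_51_P337412 and A_51_P392687 were higher in M-Wnt by 9.07 ± 0.21 and 8.70 ± 0.19, and A_51_P324814 and A_51_P242399 lower, by -9.85 ± 0.20 and -8.40 ± 0.14. In total 18724 features were called, 45.6% of those tested, 9606 higher and 9118 lower, 7333 of them by at least 2-fold. Of the 1602 transcripts with several probes, all with IDs that start with Mm_ncRNA, 546 had all of them called with a single sign, and 1 had probes called in opposite directions. No slide holds control arrays of both lines; the count was 10520 with slide as a fixed block, which ended the calls of Gcsh (0.60), Rnf125 (adjusted p = 0.12), Atp5md (-0.05), Akr1b10 (-0.62) and Ppid (-0.57), and 12478 with median centring, which ended those of Atp5md (-0.62), Akr1b10 (-0.84) and Ppid (-0.56). Leaving out E-Wnt control replicate 3 ended the call of Akr1b10 (-0.61). Sizes also moved with the processing. Over the settings Tbc1d16 ranged from -4.02 (its brightest probe) to -1.81 (the filter for all 18 arrays), Selenoh from 1.45 to 2.44, Ezr from -2.25 to -1.36 and Pate14 from -1.37 to -0.45.

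metM-Wnt against M-Wnt in control medium asks how these lines differ before withdrawal. Hspb1 was 1.81-fold higher in metM-Wnt (0.85 ± 0.18, adjusted p = 0.0058), and the transcription elongation factor subunit Supt4a was higher by 0.48 ± 0.14 (adjusted p = 0.039). Ppid was lower by -0.56 ± 0.15 (adjusted p = 0.032) and Ssbp2 by -0.40 ± 0.11 (adjusted p = 0.038). Gcsh (-0.45, adjusted p = 0.28) and Prc1 (-0.27, adjusted p = 0.83) did not pass. Probes A_51_P164219 and A_51_P260740 were higher in metM-Wnt by 4.68 ± 0.33 and 4.45 ± 0.31, and A_51_P461868 and A_51_P145453 lower, by -5.06 ± 0.14 and -4.94 ± 0.25. In total 3832 features were called, 9.33% of those tested, 2030 higher and 1802 lower, and 649 by at least 2-fold. With median centring 844 were called, 36.8% of them higher against 53% after loess, and Hspb1 (0.42, adjusted p = 0.63), Supt4a (0.15), Ppid (-0.95) and Ssbp2 (-0.77) lost their calls. The metM-Wnt arrays lie on slides of their own, so slide and line cannot be told apart; the count was 2031 and 2085 without M-Wnt control replicate 2 or 3 and 2531 without metM-Wnt control replicate 3, and of the 4 named calls only that of Hspb1 was kept with each of the 6 arrays left out in turn.

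The metM-Wnt control cells differed from M-Wnt control cells largely in the direction in which M-Wnt cells changed after withdrawal: 1082 features were called higher in both comparisons (203 expected of independent lists) and 896 lower in both (151 expected), against 65 and 24 called in opposite directions. Both comparisons use the M-Wnt control arrays, and their changes correlated at r = 0.56 across features (Spearman 0.53) with a covariance of 0.087, where simulated unchanged groups against the same controls gave r = 0.42 and a covariance of 0.0097. With separate control arrays for the comparisons, r was 0.51, 0.50 or 0.44 for M-Wnt control replicate 1, 2 or 3 used for the response and the others for the line.

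**Figure D3:**
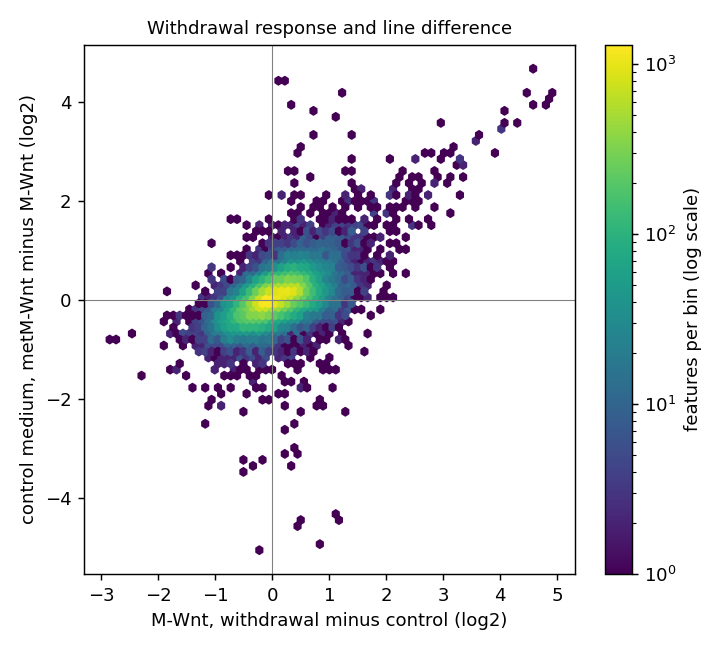
Each hexagon counts features (colour, log scale) by their log2 change after withdrawal in M-Wnt (x axis) and their log2 difference of metM-Wnt from M-Wnt in control medium (y axis). The cloud leans from lower left to upper right (r = 0.56). Both axes use the M-Wnt control arrays, and simulated unchanged groups gave a covariance of 0.0097 against 0.087 observed.

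The 3 differences in withdrawal response between lines test whether the responses differ. Hspb1 responded more in M-Wnt than in E-Wnt (difference 1.46 ± 0.25, adjusted p = 0.0024) and less in metM-Wnt than in M-Wnt (-1.15 ± 0.25, adjusted p = 0.013). Tmem41b (-1.20 ± 0.23, adjusted p = 0.0059) and Srsf10 (-0.62 ± 0.17, adjusted p = 0.044) responded more negatively in M-Wnt than in E-Wnt. Macrod2 (0.95 ± 0.19, adjusted p = 0.0078) and Pdcd10 (0.90 ± 0.22, adjusted p = 0.027) fell in M-Wnt and responded more positively in metM-Wnt. The responses of the lines hardly correlated across features, which are not independent replicates: r was -0.041 for E-Wnt and M-Wnt, -0.13 for E-Wnt and metM-Wnt, and 0.15 for M-Wnt and metM-Wnt. Counts and what they depend on are given with the results singled out for a closer look.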

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

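The tests of the slide difference, of a direction shared with replicate arrays and of the shared control arrays, and the counts of splits by whether M-Wnt arrays were mixed, were chosen after the results were seen. The results in this part were singled out because a test of the difference itself found that the response to withdrawal differed between lines.

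The response differed between M-Wnt and E-Wnt in 2820 features, 1615 with the more positive change in M-Wnt. Hspb1 (1.46), Tmem41b (-1.20) and Srsf10 (-0.62) were among them, and probes A_51_P387123 and A_52_P653054 differed by 6.52 ± 0.75 and 6.18 ± 0.80. Median centring gave 0.68 for Hspb1 (adjusted p = 0.39), and slide as a fixed block ended the calls of Hspb1 (1.29), Tmem41b (-1.34), Srsf10 (-0.78) and A_52_P653054 (5.63, adjusted p = 0.058). Within slides the calls of Hspb1, Tmem41b and Srsf10 were lost too. Slide as a random block kept them, but its correlation was negative (-0.14) and the fit raised the count, so this does not weigh against the losses. The share with the more positive change was 57.3% after loess, 43.9% of 2144 with processed signals, 41.2% of 3205 with the red channel alone and 13.8% of 1148 with median centring. The count was 229 with slide as a fixed block, 344 within slides, 6003 with slide as a random block and 1349 with a replicate block. It was 5179 without E-Wnt withdrawal replicate 3, 1621 and 1643 without M-Wnt control replicate 2 or 3, and 1722 without M-Wnt withdrawal replicate 2, and the call of Srsf10 was kept with only 3 of 12 arrays left out. Of 100 drawn splits of the arrays between media within lines, 5 gave as many calls, the real split included, so chance cannot be excluded. The highest other count was 8150, a structure in the samples. Of the other splits 6 kept the M-Wnt arrays parted by medium, and 4 of these gave as many calls as the real one. With the M-Wnt arrays mixed the highest was 929. The count thus follows mainly the split of the M-Wnt arrays.

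The response differed between metM-Wnt and M-Wnt in 2092 features, 887 with the more positive change in metM-Wnt. Macrod2 (0.95), Pdcd10 (0.90) and Hspb1 (-1.15) were among them, and probes A_51_P487690 and A_51_P164219 differed by -6.83 ± 0.62 and -6.81 ± 0.47. Slide as a fixed block ended the calls of Macrod2 (1.0), Pdcd10 (0.98) and Hspb1 (-1.39), and Pdcd10 kept its call with 4 of 12 arrays left out. Median centring ended the calls of Hspb1 (-0.69, adjusted p = 0.73), Macrod2 (1.21, adjusted p = 0.35) and Pdcd10 (1.27, adjusted p = 0.40) and left a count of 251. The red channel alone ended those of Hspb1 (-0.66, adjusted p = 0.088) and Pdcd10 (0.51, adjusted p = 0.056), and a replicate block those of Macrod2 (adjusted p = 0.073) and Pdcd10 (adjusted p = 0.099). The share with the more positive change was 42.4% after loess and 56.8% of 2305 with the red channel alone. The count was 204 with slide as a fixed block, 269 within slides, 3615 with slide as a random block and 870 with a replicate block. It was 1109 and 1122 without M-Wnt control replicate 2 or 3, 1378 and 1234 without M-Wnt withdrawal replicate 1 or 2, 1292 without metM-Wnt control replicate 3 and 1317 without metM-Wnt withdrawal replicate 2. Of 100 drawn splits 5 gave as many calls, the real one included, so chance cannot be excluded. The highest other count was 4724, and 0 with the M-Wnt arrays mixed between media. Of the other splits 10 kept the M-Wnt arrays parted by medium, and 4 of these gave as many calls as the real one. This count too follows mainly the split of the M-Wnt arrays.

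The response differed between metM-Wnt and E-Wnt in 35 features, 27 with the more positive change in metM-Wnt, and in none of the 74 named genes (limma; 5385 features at an unadjusted p under 0.05). Probes A_51_P367866 and A_52_P262219 differed by 4.95 ± 0.44 and 4.36 ± 0.38, and A_51_P286878 by -1.30 ± 0.22, a call lost with 9 of 12 arrays left out in turn. Probe A_52_P525348 was called too, but no E-Wnt array of either medium was well above background for it, so no size is given; its call was lost with 10 of 12 arrays left out. The count was 757 without E-Wnt withdrawal replicate 3, 86 without E-Wnt withdrawal replicate 2, 19 without E-Wnt withdrawal replicate 1, 12 and 22 without E-Wnt control replicate 2 or 3, 11 without metM-Wnt control replicate 1 or 2, and 13 and 19 without metM-Wnt withdrawal replicate 2 or 3. With slide as a random block 344 were called; with slide as a fixed block 4 were left, 4 with a replicate block and 0 within slides (4730 at an unadjusted p under 0.05), and all 4 were positive with median centring (77.1% after loess). Of 100 drawn splits 14 gave as many calls, with a highest other count of 2848, so chance cannot be excluded and the samples have a structure beyond the groups.

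The first pattern weighed is that more features changed after withdrawal in M-Wnt than in E-Wnt. The larger spread between E-Wnt arrays was weighed by the size of the changes. In M-Wnt the SD left after the array spread was taken off was 0.402. In E-Wnt the variance from array spread (0.0672) exceeded that of the changes (0.0547), so their whole SD (0.234) was used. The ratio was 1.72 (95% interval 1.68 to 1.75, over features that are not independent). The interval holds no variation between the arrays of a group. In these arrays the M-Wnt effects were thus larger than the E-Wnt changes. How far the ratio varies between arrays was not tested, so the larger spread is not excluded. Probe GC content does not account for the pattern, since 91.6% of the M-Wnt calls were still called with their sign after each array's GC trend was removed. A slide difference stays open: the slide with both media gave 2230 calls, but holds a single M-Wnt control array, so slide and medium cannot be told apart for the other controls, and a direction of change that also separates replicates stays open, because the M-Wnt response correlated with the deviation of E-Wnt control replicate 2 at r = 0.38. A difference between the lines in their response to the medium, folic acid and serum together, remains among the open explanations. The lower red signal of the M-Wnt withdrawal than of the M-Wnt control arrays was not tested as an explanation.

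The second pattern is that metM-Wnt control cells differ from M-Wnt control cells in the direction of the M-Wnt withdrawal response. The shared M-Wnt control arrays do not account for all of it, as the observed covariance was 8.96 times the simulated one. The slide of the M-Wnt control arrays stays open: with the controls divided by slide r was 0.44, above the bound set in advance, which a slide difference alone does not give. That value rests on a single control array on the slide of the withdrawal arrays, and single arrays of other lines deviated along the M-Wnt response at r up to 0.38. A state of the metM-Wnt cells that resembles M-Wnt cells without folic acid may be a biological explanation, and it was not tested. The lower red signal of the metM-Wnt control and M-Wnt withdrawal arrays than of the M-Wnt control arrays was not tested either.

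Other splits of the arrays were counted for the remaining comparisons. For the average over the lines 1 of 100 drawn splits, the real one, gave as many as 2841 calls, and the highest other gave 2462. Of the other splits 17 kept the M-Wnt arrays parted by medium, and with those mixed the highest count was 1. The count thus follows the M-Wnt arrays and does not show a response shared by the 3 lines. Those arrays have 10 splits, too few for a share under 0.05, so the drawn splits do not exclude chance. In E-Wnt 3 of the 10 splits gave at least 16 calls, with 2386 for E-Wnt control 1 and withdrawal 1 and 2 against the rest, which points to a structure of the E-Wnt samples other than medium. In M-Wnt (7563 calls), metM-Wnt (166), M-Wnt against E-Wnt (18724) and metM-Wnt against M-Wnt (3832) the real split was the 1 of 10 with as many calls and the highest other gave 0, and 10 splits are too few for a share under 0.05.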

How the results depend on the processing

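All alternatives in this part were planned before the data were examined. Signal over background limited the tests to 41089 of 80520 probes. Where no reason is given below, the cause was not tested.

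Of the named values called under the planned model, 1220 of 1221 kept their direction and 1044 their call over the settings other than leaving an array out. With an array left out, 636 of 636 kept their direction and 515 their call. The former settings include fits of fewer arrays (within slides, and only the groups compared). They also include settings that cannot change most values, such as Aquantile, so the share kept does not measure how stable the values were. No gene list passed under any setting (0 in each). Results not given here stayed within 1.5 times their count. Loess followed by Aquantile cannot change log ratios and gave the same counts.

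Below, counts follow the order E-Wnt, M-Wnt, metM-Wnt, average, M-Wnt against E-Wnt, metM-Wnt against M-Wnt, then the differences M-Wnt less E-Wnt, metM-Wnt less M-Wnt and metM-Wnt less E-Wnt; under the planned model they were 16, 7563, 166, 2841, 18724, 3832, 2820, 2092 and 35. Agilent processed signals gave 10 in E-Wnt, 285 in metM-Wnt and 19 for metM-Wnt less E-Wnt, and the series table gave 10, 292 and 19. Median centring without loess gave 7, then 18 in metM-Wnt, 507, 12478, 844, 1148, 251 and 4. It moved the median change of all features to -0.247 in M-Wnt, -0.174 in metM-Wnt, -0.125 in the average, -0.134 for metM-Wnt against M-Wnt, -0.352 for M-Wnt less E-Wnt and -0.239 for metM-Wnt less E-Wnt, so directions there are relative to that shift. The red channel alone gave 38 in E-Wnt, no filter 9 in E-Wnt, and the filter for all 18 arrays 95 in metM-Wnt, with fewer features tested. Robust eBayes with trend gave 15 for metM-Wnt less E-Wnt.

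Slide as a fixed block gave 6, 2023, 0, 225, 10520 for M-Wnt against E-Wnt, 229, 204 and 4, and no value for metM-Wnt against M-Wnt, whose slides hold metM-Wnt alone (3276 in metM-Wnt at an unadjusted p under 0.05). Slide as a random block (correlation -0.14) gave 106 in E-Wnt, 666 in metM-Wnt, 6695 for metM-Wnt against M-Wnt, 6003, 3615 and 344. Within the slides that hold both media the counts were 1, 2230, 0, 201, 344, 269 and 0, from 1 array in place of 3 in a group, which is assumed to vary like the others (at an unadjusted p under 0.05, limma gave 3672 in metM-Wnt and 4730 for metM-Wnt less E-Wnt); the line comparisons have no such slide. Array weights gave 25558 in M-Wnt, 944 in metM-Wnt, 6569, 11748 for metM-Wnt against M-Wnt, 8306, 11160 and 60. A minimum 2-fold change left 1011 in M-Wnt, 42 in metM-Wnt, 12, 7333, 649, 1046 and 810 by its construction. The groups compared alone gave 1 in E-Wnt, 14984 in M-Wnt, 0 in metM-Wnt (5510 at an unadjusted p under 0.05), 4520 for metM-Wnt less M-Wnt and 3 for metM-Wnt less E-Wnt, each with the spread of its own arrays.

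The replicate block within lines gave 9 in E-Wnt, 4771 in M-Wnt, 31 in metM-Wnt, 1038 for the average, 1349, 870 and 4 for the differences; for the line comparisons the block lies within a line and gives no separate value. Nothing in the labels pairs the numbers across media, and the deviations of same-numbered arrays correlated at 0.36, -0.65 and -0.17 in E-Wnt, -0.015, -0.016 and 0.13 in M-Wnt, and -0.34, -0.33 and 0.55 in metM-Wnt, with no common sign, so the numbers do not pair the samples and calls lost under this block are not read as weaker.

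With each array left out in turn the counts ranged from 6 to 159 in E-Wnt, 3994 to 6053 in M-Wnt, 17 to 133 in metM-Wnt, 1717 to 3974 for the average, 16505 to 17540 for M-Wnt against E-Wnt, 2031 to 3176 for metM-Wnt against M-Wnt, 1621 to 5179 for M-Wnt less E-Wnt, 1109 to 2441 for metM-Wnt less M-Wnt and 11 to 757 for metM-Wnt less E-Wnt. In M-Wnt, calls were also lost without control replicate 2 (Gcsh -0.79, Pdcd10 -0.58, Tbc1d16 0.49, Wfdc18 0.48), without withdrawal replicate 1 (Gcsh -0.76, Srsf10 -0.45, Wfdc18 0.56) or 2 (Gcsh -0.73, Srsf10 -0.43, Wfdc18 0.56) and without withdrawal replicate 3 (Tbc1d16 0.35, Wfdc18 0.45).

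A sign turned in these values. Median centring gave -0.10 for Wfdc18 and -0.16 for Dnajb9 in M-Wnt, and -0.29 for Gcsh and -0.14 for Hspb1 in metM-Wnt. Apart from Wfdc18, no value that turned was called under the planned model. In metM-Wnt, Gcsh was -0.01 with processed signals, -0.01 in the series table, -0.02 with slide as a fixed block and -0.02 within slides, and with an array left out it ranged from -0.23 to 0.24, negative without control replicate 2 (-0.04), control replicate 3 (-0.10) or withdrawal replicate 2 (-0.23). Prc1 in metM-Wnt was 0.06 with the red channel alone, and Hspb1 in metM-Wnt -0.04 with array weights and -0.05 without control replicate 1 (range -0.05 to 0.33 with an array left out). In E-Wnt, Prc1 was 0.78 with slide as a fixed block and within slides, 0.23 with array weights and 0.60 without withdrawal replicate 3 (range -1.01 to 0.60 with an array left out), and Hspb1 was 0.13 with slide as a fixed block and within slides. In M-Wnt, Hspd1 was 0.00 without control replicate 1, 0.06 without withdrawal replicate 1 and 0.04 without withdrawal replicate 2 (range -0.18 to 0.06).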

Other observations

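Calls were counted in groups of probes known only by their IDs; these groups and their tests were chosen after the data were seen, and the shares called were not tested against each other. After withdrawal in M-Wnt, 19.2% of 32490 probes with IDs that start with A_51 or A_52 were called, 18.7% of 6272 features from probes that start with Mm_ncRNA (534 higher, 638 lower), and 5.81% of 2220 that start with VIRS (53 higher, 76 lower). Against the other features, the VIRS probes shifted down in M-Wnt with camera's preset correlation (adjusted p = 0.0323), and this was lost with an estimated correlation (adjusted p = 0.437); the Mm_ncRNA features passed with neither (adjusted p = 0.282, and 0.221 with an estimated correlation). Between the lines in control medium 18.2% of the VIRS probes were called, against 45.6% of all features, 328 of them higher in M-Wnt than in E-Wnt and 76 lower; their shift did not pass camera (adjusted p = 0.0654, and 0.454 with an estimated correlation).

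The 38 probes called higher in M-Wnt and lower in metM-Wnt after withdrawal were also all called in the difference between those responses, and 35 of them were called higher in metM-Wnt than in M-Wnt control cells. Their median log2 ratio went from -0.242 to 1.83 in M-Wnt, from 1.62 to 0.358 in metM-Wnt, and from 0.359 to 0.0075 in E-Wnt, from control to withdrawal. Each comparison here shares arrays with another, so the overlap of calls is not independent evidence.

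Probes that repeat a sequence under another ID gave the same changes within a small difference: over 53 tested pairs, r was 0.98 for the M-Wnt response and 0.93 for the E-Wnt response, with median differences of 0.049 and 0.037 log2 units.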
